A study of Mus musculus with 11 samples.

How the data were processed

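RNA was measured in E14 mouse embryonic stem cells, an established cell line, in wild-type cells (WT) and in cells labelled as Prmt1 knockouts. The labels give 3 bulk libraries each for WT, KO1 and KO2, and 1 droplet single-cell library each for WT and for the knockout. They place the cells in serum medium with LIF. They do not say whether KO1 and KO2 are separate clones, nor whether the 3 replicates of a group are separate cultures. The p-values given here therefore measure only the spread between these libraries, which may be technical.

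The deposited bulk table holds raw counts per gene symbol, whole numbers that sum to between 27029808 and 33163881 per library. The authors' processing notes name HISAT2 and the genome build mm10 for bulk and single-cell samples together. The counting program, the strand setting, the annotation and all versions are not given in the sources used here, so antisense reads cannot be set apart from sense reads. Symbols were matched to positions in the mouse GENCODE annotation of the same build, which placed 91.4% of the 17085 genes tested.

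The deposited single-cell table holds a score per gene and cell and not counts, although it is described as normalized counts. Each gene was centred near 0 and scaled to a standard deviation of at most 1, and the values were clipped at 10. The authors' notes name Cell Ranger and Seurat, without versions, filters or the covariates removed. Tests on the values showed that 3 covariates had been removed by regression and that these fix the barcode suffix exactly. Before clipping, the mean of every gene is therefore equal in both suffix sets by construction. No label says which suffix belongs to which library, so the cells were described as 1 pooled sample of 13805 cells and no WT value was set against a knockout value. Cells without a transcript of a gene lie on 1 plane in the removed covariates. Detection per cell was recovered from that plane for 18404 of 18696 genes, those with at least 50 cells within 1e-06 of it. In simulated data of 3000 cells this gave every cell correctly for 365 of 365 genes resolved.

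Bulk counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM factors, 1 quasi-likelihood fit with robust dispersions over the 9 libraries, and Benjamini-Hochberg adjustment with a threshold of 0.05 and no fold threshold. Contrasts were KO1 against WT, KO2 against WT, the mean of both knockouts against WT, and KO2 against KO1. Levels are in CPM, counts per 1e6 counts of the TMM-scaled library size, as the mean and standard deviation (SD) of 3 libraries, and fold changes are log2 with their standard error (SE). For a gene with 0 counts in WT, the fold is a lower bound against a floor of 3 counts over the group. For 1 to 3 counts in WT, in a knockout for the largest falls, or in KO1 against KO2, the ratio of CPM is given with its exact 95% counting interval. Such intervals and floors, and the exact binomial (Clopper-Pearson) intervals of cell shares, cover counting error only. For a share of 0 cells the limit is 3 cells of the total. The overlap of the KO1 and KO2 calls was set against the product of their shares and against 20 simulations in which unchanged groups shared the WT libraries. In simulated data the mean contrast recovered 80.0% of genes changed 1.5-fold, 94.0% at 2-fold and 100.0% at 4-fold, with 13 false calls among 16082 genes. Only 200 genes were changed there, each with a simulated mean of at least 1 CPM, far fewer than were called in the data. Recovery in the data may therefore differ. The common biological coefficient of variation was 8.10%.

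Before the data were examined, 26 gene lists, the single-cell markers, the tests, the alternatives and the rule for named genes were written down. The lists were naive, general, and formative and primed pluripotency; primitive, parietal and visceral endoderm; mesendoderm and mesoderm; neuroectoderm; trophoblast; 2-cell-like; fibroblast (feeder); germline; the PRMT family; p53 targets; DNA replication; mitosis; the integrated stress response; cholesterol synthesis; glycolysis and hypoxia; interferon response; FGF and ERK, LIF and STAT3, Wnt and BMP targets; imprinted; and Y-linked genes. Each was tested with camera (limma 3.58.1, voom values, preset correlation of 0.01) and again with an estimated correlation, with adjustment over the lists. Genes were named by this rule: Prmt1; the 10 highest and 10 lowest called in both knockouts by the smaller of both fold changes, with a mean of at least 1 CPM and no overlap with WT; 5 of each direction for KO2 against KO1, and for genes called in only 1 knockout and in KO2 against KO1; and up to 4 members of each list with the smallest adjusted p. Some genes that the rule names are not reported here. The rule left out predicted genes, ribosomal protein genes and histone genes. List members named outside this rule illustrate a count and were chosen after their values were seen.

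The deposited scores were clustered in Python 3.11.15 with the Leiden algorithm (leidenalg 0.10.2). Settings were 2000 variable genes, 30 components, 15 neighbours and a resolution of 0.5. The recovered detection gave the shares of cells with a gene and the marker counts that named clusters. Clusters were named only from the fixed markers. No doublet caller was run, since such callers need counts.

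Alternatives for factors and filters were relative log expression (RLE) factors in edgeR, upper-quartile factors, no filter, and a filter of at least 5 CPM in 3 libraries. Alternatives for the test were the DESeq2 (1.42.0) Wald test, limma-voom and a threshold of 1 on the absolute log2 fold change. Further alternatives were fits of only the groups compared, a replicate block, and leaving out each library in turn. Replicate numbers did not pair the libraries. Residual correlations between libraries that share a number ran from -0.152 to 0.157, and 2 of 9 libraries were most similar to one with their own number. After the data were seen, alternatives were added that remove the median shift of each chromosome or of the 40 nearest genes, and chromosome bins were examined. Chromosome, bin and segment values use the 9131 protein-coding genes on the autosomes and X with a mean log2 CPM over 3.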

Results

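Bulk RNA was counted in 9 libraries of mouse embryonic stem cells, 3 each of WT, KO1 and KO2, and a pooled single-cell table held 13805 cells. Total counts ran from 32338400 to 33163881 in WT, from 27950518 to 32343731 in KO1 and from 27029808 to 32594779 in KO2. The 10 most abundant genes took between 6.58% and 7.63% of a library. Of 46095 gene symbols, 28174 had a count and 17085 were tested. The first principal component held 75.3% of the variance and placed WT between -98.0 and -94.0, KO1 between 50.7 and 53.4 and KO2 between 42.2 and 47.7. Spearman correlations across genes ran from 0.943 to 0.946 within groups, from 0.942 to 0.944 between KO1 and KO2, and from 0.922 to 0.927 between WT and either knockout.

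Prmt1, the main type I protein arginine methyltransferase of mammalian cells (chromosome 7, 44975989 to 44986568, mm10), fell from 127.6 ± 3.42 CPM in WT to 16.5 ± 2.14 in KO1 and 16.5 ± 2.42 in KO2 (mean ± SD, n = 3 libraries each). The log2 fold change was -2.95 (SE 0.09, edgeR adjusted p = 2.27e-20) in KO1 and -2.95 (SE 0.09, edgeR adjusted p = 2.75e-20) in KO2. Transcript at 12.9% of the WT level thus remained in both groups. The counts do not show whether it carries the targeted edit.

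**Figure D1:**
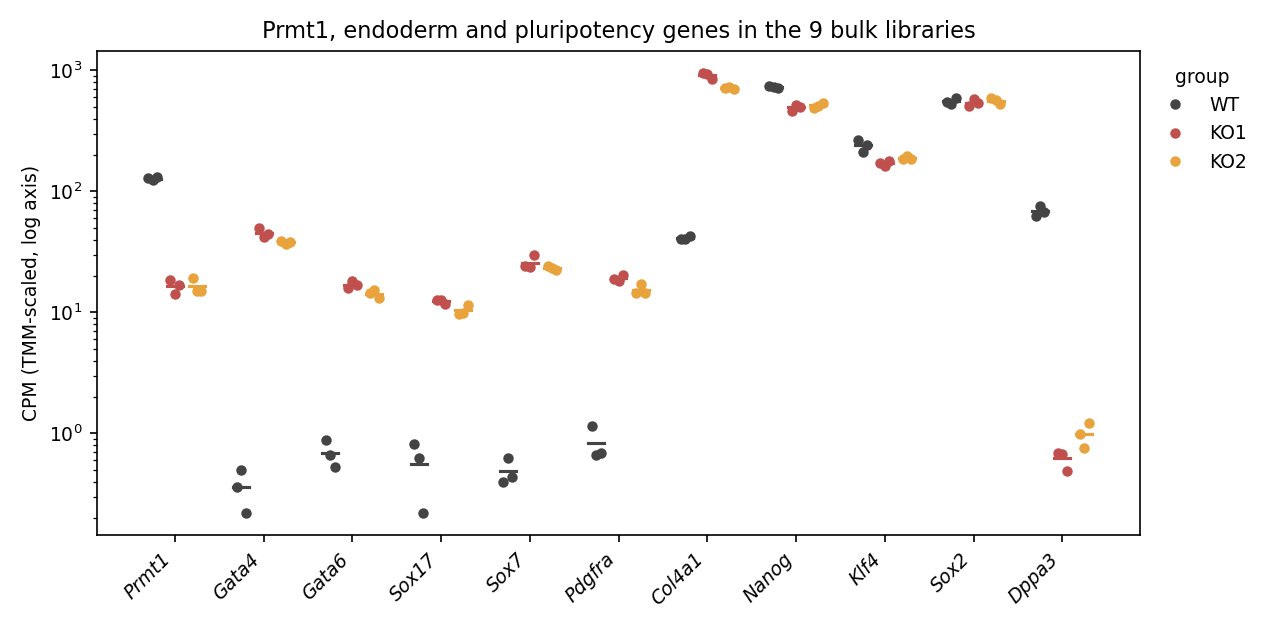
CPM (log axis) of 11 genes in the 9 bulk libraries, with 1 point per library and a line at the mean of each group. Prmt1 lies near 16.5 CPM in both knockouts against 127.6 in WT, and Gata4 lies at 45.6 and 38.0 CPM against 0.362.

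The comparison of KO1 with WT asks what differs in the transcriptome of a Prmt1 knockout. Higher in KO1 were 13 of 14 genes each of primitive and of parietal endoderm and all 11 tested genes of a 2-cell-like state, while visceral endoderm genes went both ways. Lower were 9 of 15 naive pluripotency genes (2 were higher), 14 of 15 cholesterol synthesis genes and all 5 tested Y-linked genes. Gata4, a transcription factor of primitive endoderm, rose from 0.362 ± 0.142 to 45.6 ± 4.12 CPM (n = 3 each; log2 fold change 6.96, SE 0.15). Dppa3, a marker of naive pluripotency and of germ cells, fell from 68.4 ± 6.53 to 0.621 ± 0.111 CPM (log2 fold change -6.78, SE 0.15). In the edgeR fit 11114 of 17085 genes were called, 5688 higher and 5426 lower, of which 2118 were higher and 2090 lower by at least 2-fold. Camera called 10 lists, none of them with an estimated correlation (lowest adjusted p = 0.0550 with an estimated correlation).

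In KO2 the same lists moved mostly the same way against WT, with 10 of 15 naive pluripotency genes lower. Gata4 stood at 38.0 ± 1.04 CPM in KO2 (n = 3; log2 fold change 6.70, SE 0.15) and Dppa3 at 0.990 ± 0.229 CPM (log2 fold change -6.11, SE 0.14). The edgeR fit called 10938 genes, 5527 higher and 5411 lower, of which 2095 were higher and 1940 lower by at least 2-fold. Camera called 11 lists, none of them with an estimated correlation (lowest adjusted p = 0.0548 with an estimated correlation). The added list was the interferon response (adjusted p = 0.0410, against 0.141 in KO1 and 0.122 for the difference between KO2 and KO1). Both comparisons use the same 3 WT libraries.

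Genes called in the same direction in both knockouts numbered 9837, with 4999 higher (1840 under independence) and 4838 lower (1718 under independence), and 3 genes were called in opposite directions. Fold changes correlated across genes with r = 0.956, against 0.495 in simulations where only the WT libraries were shared; genes are not independent replicates. The covariance of the fold changes was 1.54, against 0.0301 in those simulations, and 91.7% of genes shared a sign, against 66.5%. No gene was changed in the simulations, and the median number called was 0 in KO1 and 0 in KO2. That at most 1 gene was called in both in any of the 20 was therefore fixed by their design. It does not measure the overlap of 2 knockouts that each change many genes.

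Among the 10 genes with the largest rise in both knockouts were Gata4, Enpep (a glutamyl aminopeptidase), Cdh5 (the endothelial cadherin) and Slc34a2 (a phosphate transporter). Amy1, an amylase gene, had 0 counts in WT and was at least 119-fold higher in KO1 and at least 96.7-fold higher in KO2, and Ccdc168 was at least 51.8-fold and 62.2-fold higher. Enpep had 1 count in WT, and its ratio to WT was 998 (interval 179 to 39455) in KO1 and 826 (148 to 32684) in KO2. Slc34a2, also with 1 WT count, had ratios of 266 (47.3 to 10557) and 216 (38.3 to 8565). Nostrin, with 2 counts, had ratios of 317 (87.5 to 2627) and 241 (66.4 to 1997), and Timd2, with 3, had 129 (43.9 to 629) and 155 (52.8 to 756). Cdh5 rose from 0.0823 ± 0.0338 to 19.4 ± 1.23 and 17.3 ± 0.779 CPM (n = 3 each). Clic5 rose by 6.65 and 6.34 on the log2 scale, and Glipr1 by 6.73 and 6.32.

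The 10 largest falls included 3 Y-linked genes (Ddx3y, Uty and Zfy1), the imprinted genes Plagl1 and Nnat, and Dppa3. Plagl1, a zinc finger gene expressed from the paternal allele, fell from 21.3 ± 2.41 to 0.230 ± 0.232 and 0.173 ± 0.0887 CPM (n = 3 each). Nnat fell from 8.88 ± 0.676 to 0.0844 ± 0.0781 and 0.148 ± 0.0493 CPM. Meiob, a meiotic recombination gene with 715 counts in WT, had 3 counts in KO1 (ratio to WT 0.00447, interval 0.000919 to 0.0131) and 1 in KO2 (0.00151, 3.81e-05 to 0.00843). Ikzf1, a lymphoid transcription factor, had a log2 fold change of -5.80 in KO1 and 2 counts in KO2 (ratio 0.00681, 0.000821 to 0.0248). Dnajc5g had log2 fold changes of -6.64 and -6.39, and Mtl5 of -5.57 and -6.39.

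Gene lists were compared between the mean of both knockouts and WT, the genotype contrast that the study design names. Markers of primitive endoderm, the extraembryonic lineage that forms beside the epiblast, were higher in both knockouts. Of 14 members 13 rose, 0 fell and 1 was not called, with 13 and 0 adjusted over the list alone, and the median log2 fold change was 4.08. Gata6 rose from 0.691 ± 0.175 to 16.9 ± 1.10 CPM in KO1 and 14.3 ± 1.14 in KO2 (n = 3 each), Sox17 from 0.556 ± 0.306 to 12.3 ± 0.561 and 10.4 ± 1.01, and Cubn, the endocytic receptor cubilin, from 0.662 ± 0.224 to 63.0 ± 3.79 and 52.9 ± 4.48. Cited1 was not called (log2 fold change 0.37, SE 0.28, adjusted p = 0.248). Gata4 and Sox7 (log2 fold changes 6.83 and 5.65) lie in a segment of chromosome 14 whose genes had a median 2.14-fold higher, and their 40 nearest genes had medians of 1.08 and 0.94. Camera called the list (adjusted p = 2.40e-07), but not with an estimated correlation (adjusted p = 0.0629 with an estimated correlation).

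Parietal endoderm genes, mostly of basement membrane and its secretion, were higher as well. Of 14 members 13 rose, 0 fell and 1 was not called, with 13 and 0 adjusted over the list alone, and the median log2 fold change was 3.36. Col4a1, a chain of type IV collagen, rose from 41.4 ± 1.60 to 912 ± 60.6 CPM in KO1 and 714 ± 7.81 in KO2 (n = 3 each), and Srgn from 2.70 ± 0.615 to 40.3 ± 1.88 and 32.7 ± 1.11. Nid1 had a log2 fold change of -0.00 and was not called. The camera adjusted p was 7.64e-08, and the adjusted p = 0.0629 with an estimated correlation. Visceral endoderm genes went both ways: of 7 members tested 3 rose, 3 fell and 1 was not called, with 3 and 3 adjusted over the list alone (camera adjusted p = 0.850). Amn, the partner of cubilin, rose by 2.58 on the log2 scale, while Rbp4 and Hhex had log2 fold changes of -1.47 and -0.63. Afp, Ttr and 5 other members had too few counts to test.

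**Figure D2:**
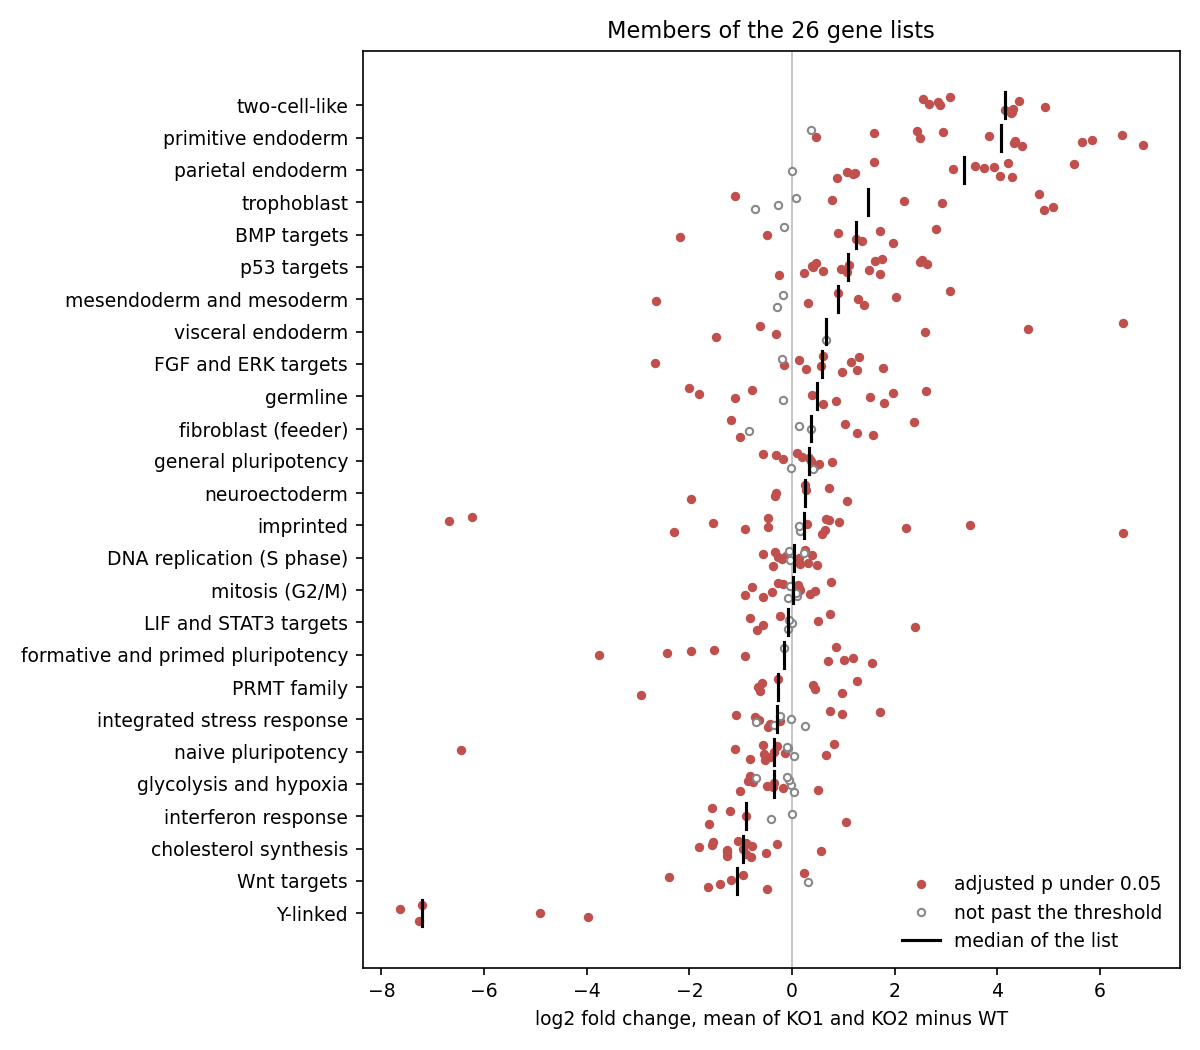
Log2 fold change of each tested member of the 26 gene lists, mean of KO1 and KO2 minus WT, with filled points for adjusted p under 0.05 and a bar at the median of each list. The medians are 4.08 for primitive endoderm, 3.36 for parietal endoderm, 4.16 for 2-cell-like genes and -7.21 for Y-linked genes.

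Naive pluripotency genes were mostly lower. Of 15 members 2 rose, 10 fell and 3 were not called, with 2 and 10 adjusted over the list alone, and the median log2 fold change was -0.36. Nanog fell from 728 ± 18.2 to 494 ± 28.1 CPM in KO1 and 513 ± 26.9 in KO2 (n = 3 each), Esrrb from 1011 ± 134 to 664 ± 12.3 and 729 ± 6.92, and Klf4, the factor named in the study title, from 239.9 ± 28.0 to 171 ± 8.15 and 189 ± 5.47, while Tbx3 rose by 0.65. The camera adjusted p was 0.0265, and the adjusted p = 0.353 with an estimated correlation; a filter of 5 CPM also ended the call (adjusted p = 0.0563). Nanog (log2 fold change -0.53) and Dppa3 lie in the lowered part of chromosome 6, where the 40 nearest genes of Nanog had a median of -0.52. With chromosome medians removed 2 members were higher and 11 lower. For chromosome 6 this removed -0.35 in KO1 and -0.26 in KO2, against medians of -0.52 and -0.43 in its lowered part. Part of the local shift thus stayed in Nanog and Dppa3. Of 13 general pluripotency genes 8 rose, 3 fell and 2 were not called, with 8 and 3 adjusted over the list alone (camera adjusted p = 0.151). Lin28a and Dppa2 rose by 0.53 and 0.78, and Sox2 was not called (log2 fold change -0.01, SE 0.05). Pou5f1, which embryonic stem cells express at a high level, had only 74 to 216 counts per library, so it rests on few reads. Formative and primed genes split into 5 higher, 5 lower and 1 not called of 11, with 5 and 5 adjusted over the list alone (camera adjusted p = 0.850, direction up, against a median of -0.15): Otx2 rose by 1.56 and Dnmt3b by 1.02, while Zic2 had -3.77 and Lef1 -1.98.

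Genes of a 2-cell-like state, a rare state of embryonic stem cell cultures, were higher. All 11 members tested rose, with 11 and 0 adjusted over the list alone, and the median log2 fold change was 4.16. Zscan4d rose from 0.479 ± 0.383 to 11.4 ± 0.737 CPM in KO1 and 7.97 ± 0.643 in KO2 (n = 3 each), and Zfp352 from 0.143 ± 0.142 to 1.25 ± 0.403 and 0.915 ± 0.424. The Zscan4 genes are close paralogs, so reads may be shared among them. The camera adjusted p was 0.000349, and the adjusted p = 0.137 with an estimated correlation.

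Lists of other lineages were not called by camera. Of 10 trophoblast genes 6 rose, 1 fell and 3 were not called, with 6 and 1 adjusted over the list alone (adjusted p = 0.133). Gata3 rose by 5.09, and the keratins Krt8 and Krt18, which endoderm also expresses, by 2.91 and 2.19. Of 9 mesendoderm and mesoderm genes 6 rose, 1 fell and 2 were not called, with 6 and 1 adjusted over the list alone (adjusted p = 0.394), among them Hand1 by 3.08. Neuroectoderm genes had 4 higher and 3 lower of 7, with 4 and 3 adjusted over the list alone (adjusted p = 0.850, direction up, median 0.26, mean -0.05). Sox11 rose by 0.71 and Pax6 had -1.98. With chromosome medians removed 3 of these genes were higher and 4 lower, and the median was -0.24. Germline genes had 7 higher, 4 lower and 1 not called of 12, with 7 and 4 adjusted over the list alone (adjusted p = 0.394), among them Ddx4 by 1.78 and Taf7l by 2.62. Of 9 fibroblast genes 4 rose, 2 fell and 3 were not called, with 4 and 2 adjusted over the list alone (adjusted p = 0.613), and Col1a1, their most abundant collagen, on chromosome 11, had a log2 fold change of -1.02 (-0.52 with chromosome medians removed).

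Transcriptional targets of p53 were higher with 1 exception. Of 16 members 15 rose and 1 fell, with 15 and 1 adjusted over the list alone, and the median log2 fold change was 1.09. Perp rose from 16.1 ± 1.15 to 104 ± 5.06 CPM in KO1 and 83.3 ± 3.46 in KO2 (n = 3 each), and Mdm2 and Plk2 by 1.71 and 2.50, while Cdkn1a, which encodes the cell cycle inhibitor p21, had -0.25. The camera adjusted p was 3.07e-07, and the adjusted p = 0.101 with an estimated correlation. Cholesterol synthesis genes were lower: 14 of 15 fell and 1 rose, with 14 and 1 adjusted over the list alone, and the median was -0.96. Dhcr7 fell from 181 ± 12.9 to 55.8 ± 4.17 and 67.2 ± 5.14 CPM and Sqle from 174 ± 11.4 to 68.8 ± 2.13 and 75.3 ± 6.40, while Fdft1, in the raised segment of chromosome 14, rose by 0.56 (its 40 nearest genes had a median of 1.23). The camera adjusted p was 3.39e-07, and the adjusted p = 0.301 with an estimated correlation.

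Signalling targets moved in different directions. FGF and ERK targets had 9 higher, 2 lower and 1 not called of 12, with 9 and 2 adjusted over the list alone, and camera called them (adjusted p = 0.0265; adjusted p = 0.315 with an estimated correlation). Dusp6 rose from 24.1 ± 1.76 to 86.2 ± 7.18 CPM in KO1 and 79.8 ± 3.93 in KO2 (n = 3 each), Spry4 rose by 1.28, and Egr1, an immediate early gene, fell from 79.2 ± 2.94 to 10.4 ± 1.66 and 14.9 ± 0.966 CPM. Wnt targets had 1 higher, 6 lower and 1 not called of 8, with 1 and 6 adjusted over the list alone, and camera called them lower (adjusted p = 0.0368; adjusted p = 0.192 with an estimated correlation); Notum had -2.40 and Tcf7 -1.18. Both lie on chromosome 11, which was lower as a whole, and with chromosome medians removed 1 member was higher and 5 lower, the list median went from -1.07 to -0.56 and Tcf7 to -0.68. Of 9 BMP targets 6 rose, 2 fell and 1 was not called, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.0946); Id1 rose by 1.97 and Id4 had -2.18. LIF and STAT3 targets had 3 higher, 4 lower and 3 not called of 10, with 3 and 4 adjusted over the list alone (camera adjusted p = 0.850, direction down; median -0.07, mean 0.12), with Gbx2 at 2.39 and Socs3, on chromosome 11, at -0.69 (-0.18 with chromosome medians removed). A filter of 5 CPM ended the calls of the FGF and ERK list and of the Wnt list (adjusted p = 0.0563 for each).

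Glycolysis and hypoxia genes had 1 higher, 8 lower and 5 not called of 14, with 1 and 8 adjusted over the list alone. Hk2, a hexokinase, had a log2 fold change of -1.02 and Tpi1 of -0.81, while Pfkl rose by 0.50. Hk2, Gapdh and Tpi1 lie in the lowered part of chromosome 6, and with chromosome medians removed 1 member was higher and 7 lower, and Tpi1 had -0.50. The medians removed for chromosome 6 were -0.35 in KO1 and -0.26 in KO2, against -0.52 and -0.43 in its lowered part. Part of the local shift thus stayed in these values. Camera called the list (adjusted p = 0.0265; adjusted p = 0.315 with an estimated correlation), but not at a filter of 5 CPM (adjusted p = 0.0563). Interferon response genes had 1 higher, 4 lower and 2 not called of 7, with 1 and 4 adjusted over the list alone (camera adjusted p = 0.0884); Ifitm3 had a log2 fold change of -1.55 and Irf1, on chromosome 11, of -1.22 (-0.71 with chromosome medians removed). Integrated stress response genes had 3 higher, 6 lower and 5 not called of 14, with 3 and 6 adjusted over the list alone (camera adjusted p = 0.613). DNA replication genes had 7 higher, 6 lower and 3 not called of 16, with 7 and 6 adjusted over the list alone (camera adjusted p = 0.975), and mitosis genes had 6 higher, 6 lower and 4 not called of 16, with 6 and 6 adjusted over the list alone (camera adjusted p = 0.850, direction down; median 0.02, mean -0.07). Mcm3, on chromosome 1, rose by 0.49, but had -0.02 once the median shift of its chromosome was removed, an alternative chosen after seeing the data.

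Imprinted genes changed in both directions, with 9 higher, 7 lower and 2 not called of 18, and 9 and 7 adjusted over the list alone (camera adjusted p = 0.808, direction up; median 0.23, mean -0.13). Igf2 rose from 0.341 ± 0.134 to 37.2 ± 1.25 CPM in KO1 and 24.4 ± 1.32 in KO2 (n = 3 each), Cdkn1c rose by 3.46 and Peg10 by 2.23. Meg3 was called in the mean contrast (log2 fold change -2.31, SE 0.73, adjusted p = 0.0279), but WT replicate 1 held 1799 of its counts against 227 and 230 in the other WT libraries. Of the 9 PRMT family genes 4 rose and 5 fell, with 4 and 5 adjusted over the list alone (camera adjusted p = 0.613): Prmt8 rose by 1.27 and Carm1 by 0.44, while Prmt5 had -0.66. Prmt5 lies in a segment of chromosome 14 whose genes had a median 0.577-fold of WT.

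All 5 tested genes of the Y-linked list were lower in both knockouts (5 of 5 adjusted over the list alone; camera adjusted p = 0.000155; adjusted p = 0.0629 with an estimated correlation). Ddx3y fell from 88.3 ± 6.04 to 0.434 ± 0.109 CPM in KO1 and 0.756 ± 0.0538 in KO2 (n = 3 each), and Eif2s3y from 114 ± 2.32 to 8.06 ± 0.512 and 6.59 ± 1.65. Of the 7 genes tested on chromosome Y, the highest level kept was 9.41% of WT, for Zfy2 in KO2.

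The mean contrast as a whole called 11730 of 17085 genes in the edgeR fit, 5938 higher and 5792 lower, of which 2138 and 2109 changed by at least 2-fold. Entire chromosomes differed as well, judged by 9131 protein-coding genes with a mean log2 CPM over 3. The median log2 fold change of chromosome 1 was 0.50 in KO1 and 0.52 in KO2 over 535 genes, and that of chromosome 11 was -0.50 and -0.52 over 753 genes. Medians of 17 other chromosomes lay between -0.07 and 0.16. Chromosome 6 had medians of -0.35 and -0.26, with 126 genes before 56.9 Mb at 0.15 and 0.19 and 294 genes between 56.9 and 149 Mb at -0.52 and -0.43. On chromosome 14, 50 genes between 52.2 and 55.9 Mb had medians of -0.81 and -0.83, and 51 genes between 55.9 and 65.8 Mb, where Gata4 and Sox7 lie, had 1.10 and 1.14. On chromosome 18, 11 genes between 12.8 and 21.0 Mb had -0.82 and -0.86. Outside chromosomes 1, 6 and 11, 7 of 340 bins of neighbouring genes shifted by at least 0.5 in both knockouts, against at most 2 in 1000 shuffles of gene order.

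**Figure D3:**
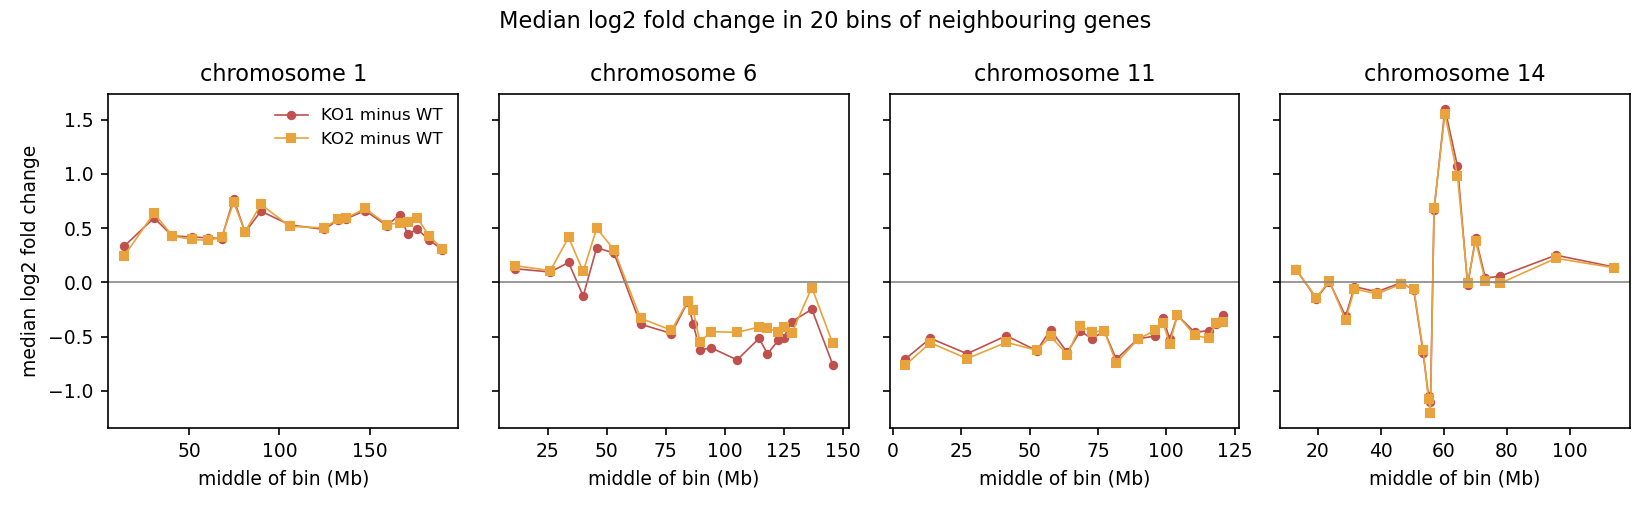
Median log2 fold change of KO1 and KO2 minus WT in 20 bins of neighbouring genes along chromosomes 1, 6, 11 and 14 (position in Mb). Chromosome 1 is raised and chromosome 11 lowered in all of their bins, and chromosome 14 has a lowered and a raised segment side by side.

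KO2 was compared with KO1 directly, which is also the test of whether their effects against WT differ. The type IV collagen genes Col4a1 and Col4a2 and the keratin genes Krt8 and Krt18 were lower in KO2, and Tex13 was higher. Col4a1 stood at 714 ± 7.81 CPM in KO2 against 912 ± 60.6 in KO1 (n = 3 each; log2 fold change -0.35, SE 0.05), and Krt18 at 39.3 ± 1.41 against 57.2 ± 4.14 (-0.54, SE 0.07). Tex13, expressed in testis, stood at 38.5 ± 2.15 against 16.2 ± 1.23 (1.25, SE 0.10). The edgeR fit called 286 genes, 168 higher and 118 lower, of which 16 and 3 differed by at least 2-fold. The count fell to 158 without KO1 replicate 1, 113 without KO1 replicate 2, 144 without KO1 replicate 3, 107 without KO2 replicate 2 and 112 without KO2 replicate 3, and it was 498 with the DESeq2 Wald test. Chromosomes 6 and 8 were higher in KO2 by medians of 0.10 and 0.07, in 20 and 19 of their 20 bins. Smaller differences were found elsewhere. Chromosome 2 had a median difference of -0.036 with 1 of 20 bins higher in KO2, and chromosome 12 had 0.037 with 18 of 20 bins higher. On both, the library medians of KO1 and KO2 did not overlap. The same held for other chromosomes, among them 4, 7, 13 and 16, with 2 of 20 bins higher in KO2 on chromosome 7 and 17 on chromosome 13. Chromosomes 2 and 12 are thus not set apart by this. The library medians against WT ran from -0.373 to -0.334 in KO1 and from -0.255 to -0.251 in KO2 for chromosome 6, and from 0.0915 to 0.108 and from 0.150 to 0.190 for chromosome 8. Lrguk, Rassf4 and Prmt8 on chromosome 6 and Ncan on chromosome 8 are among the genes higher in KO2.

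Camera called 7 lists between KO2 and KO1. Lower in KO2 were parietal endoderm (adjusted p = 1.50e-08; 5 of 14 genes lower and 7 adjusted over the list alone), primitive endoderm (adjusted p = 8.95e-05; 1 of 14 lower and 4 adjusted over the list alone), trophoblast (adjusted p = 0.000350; 2 of 10 and 4 adjusted over the list alone) and 2-cell-like genes (adjusted p = 8.95e-05; 0 of 11 and 0 adjusted over the list alone). With an estimated correlation the adjusted p was 0.0870, 0.0963, 0.0870 and 0.115 in that order. Lower too were p53 targets (adjusted p = 0.00269; adjusted p = 0.328 with an estimated correlation; 1 of 16 lower and 4 adjusted over the list alone) and integrated stress response genes (adjusted p = 0.000556; adjusted p = 0.552 with an estimated correlation; 1 of 14 lower and 1 adjusted over the list alone). Cholesterol synthesis genes were higher in KO2 (adjusted p = 4.81e-09; adjusted p = 0.257 with an estimated correlation; 2 of 15 higher and 7 adjusted over the list alone). The median differences of these lists lay between -0.39 and 0.19 on the log2 scale.

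In the pooled single-cell table, stem cell transcripts were detected in most cells, and 2 small clusters stood apart. Free RNA in droplets could not be estimated without counts, so a transcript detected in a cell need not come from it. At least 3 of 13 primitive endoderm markers were detected in 9.32% of the 13805 cells. A cluster of 109 cells, 0.790% of 13805 (exact interval 0.649% to 0.952%), had these transcripts detected together. A median of 11 of the 13 markers was detected per cell, against 1 in cells outside both small clusters. Gata6 was detected in 90.8% of its cells against 1.18% outside, Gata4 in 83.5% against 0.676% and Sox17 in 88.1% against 0.602%. Of 6 resolved stem cell markers a median of 3 was detected per cell of the cluster, against 5 outside. Nanog was detected in 22.9% against 85.0% and Sox2 in 31.2% against 90.7%. Zfp42 and Klf2 were still detected in most cells of the cluster, 79.8% against 99.4% and 73.4% against 98.3%. Median genes detected were 3640 in the cluster and 3411.5 outside; counts per cell are not in the table, so depth was not matched. Apart from predicted genes, the genes most enriched in the cluster were Bmper, Adora1, Tfec, Habp2, Igf1, Timd2 and Havcr1. Of the visceral endoderm markers, Amn was detected in 72.5% against 3.49%. The others did not share this: Rbp4 was detected in 8.26% against 13.2% and Trf in 3.67% against 11.8%. Afp was detected in 2.75% against 0.492%, Ttr in 4.59% against 0.955%, and Apoa1 and Apob in 0 cells of the cluster.

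A cluster of 84 cells, 0.608% of the table (0.486% to 0.753%), had 2-cell-like transcripts detected. Zscan4c was detected in 54.8% of its cells against 0.272% outside, Zscan4f in 53.6% against 0.389% and Zscan4d in 38.1% against 0.316%, with median genes detected of 2854.5 against 3411.5. Markers of visceral endoderm, trophoblast, mesendoderm, neuroectoderm and fibroblasts were not used to name a cluster. Prmt1 was detected in 8413 cells (60.9%, 60.1% to 61.8%). Detection of Pou5f1 and Dppa5a could not be recovered, since fewer than 50 cells lay on the plane of cells without a transcript. In the simulated data this befell only genes with fewer than 50 cells without a transcript, so both may be detected in nearly every cell. Both small clusters held 0 of the 5930 cells with barcode suffix 1, which allows a share of up to 0.0506% (3 cells; the exact upper limit is 0.0622%), and 1.38% and 1.07% of the 7875 cells with suffix 2. Since no label ties a suffix to WT or to the knockout, this is no comparison of genotypes, and a cluster from 1 suffix may reflect its library.

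**Figure D4:**
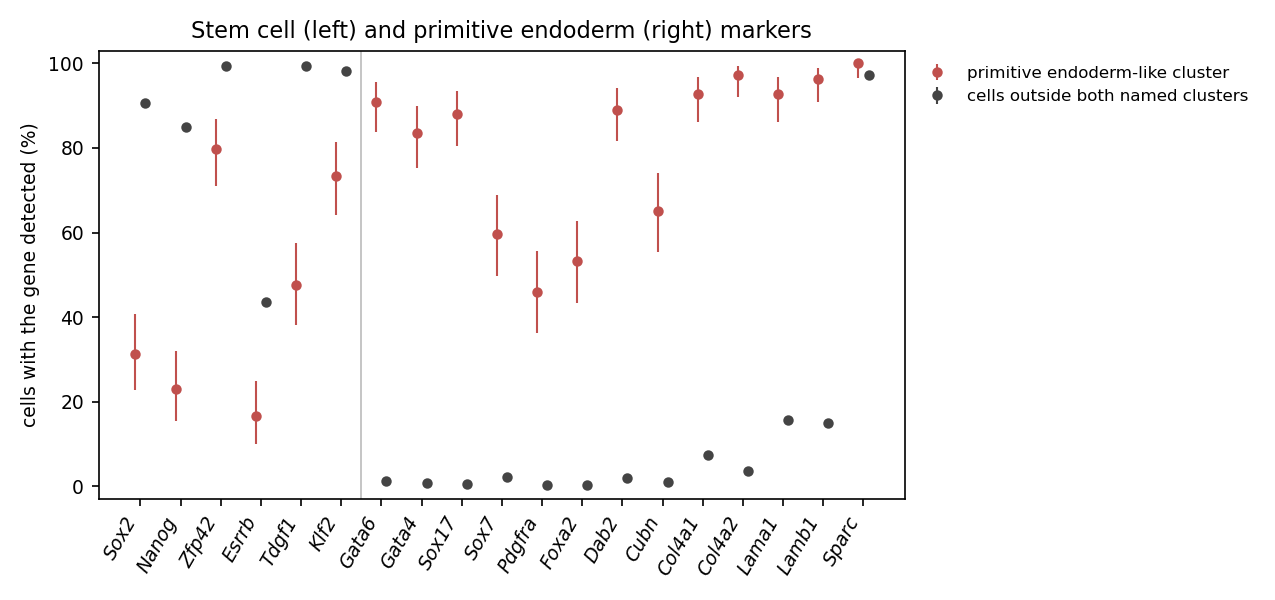
Share of cells in which each resolved stem cell and primitive endoderm marker was detected, in the primitive endoderm-like cluster (109 cells) and in cells outside both named clusters, with exact 95% intervals. Gata4 is detected in 83.5% of the cluster and 0.676% of the other cells, and Nanog in 22.9% and 85.0%.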

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

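The tests of Y-linked genes, and those of chromosome shifts, neighbouring genes and fibroblast RNA for the primitive endoderm list, were chosen only after the result was seen. The bounds for markers in single cells and the splits of the libraries were fixed before their results. Chromosomes 1, 6 and 11 were picked because their medians had shifted, and the bounds for their tests were written before those results.

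Primitive endoderm genes were higher in both knockouts. After removing the median shift of each chromosome, 13 members stayed called higher, and 12 exceeded the median of their 40 nearest genes by over 1 on the log2 scale, which argues against chromosome-wide or local shifts as the whole cause. Fibroblast RNA as the source is argued against by Col1a1, Col1a2 and Col3a1, collagens abundant in fibroblasts, which together stood at 3.14 ± 0.0509 CPM in KO1 and 3.672 ± 0.785 in KO2 (n = 3 each), under the median gains of 17.26 and 14.04 CPM of the list. The higher log2 fold change of Col1a1 in the 2 knockouts was -0.874, but the gene lies on chromosome 11, which was lower as a whole (its mean log2 fold change went from -1.02 to -0.52 with chromosome medians removed), and of 9 fibroblast genes 4 rose, among them Thy1, Col6a1 and Twist1, and 2 fell. A biological explanation, that some cells took on an endoderm state while others did not, stays open. Among single cells with barcode suffix 2, those with Gata4 had 3 or more other markers 7.61 times as often as those without it. This lies between the bounds of 2 and 10 set beforehand. Suffix 1 held 2 cells with Gata4, of which 0 had 3 others, and was left out by a minimum of 10 such cells. That minimum was not written with the bounds. Outside both small clusters the markers Sparc, Lama1 and Lamb1 were detected in 97.3%, 15.6% and 15.0% of cells. Cells without Gata4 can thus reach 3 markers through genes that are common in all cells. The cluster of 109 cells, with a median of 11 of 13 markers, is tied to no genotype. Whether loss of Prmt1 or another difference shared by KO1 and KO2 raised the primitive endoderm genes was not tested, since both also share the chromosome shifts.

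Chromosomes 1 and 11 shifted as wholes in both knockouts, by median folds of 1.42 and 0.706. All 40 of 40 bins of neighbouring genes moved the way of their chromosome, which is consistent with a difference in copy number in part or all of the cells. GC content and transcript length are argued against, since their trend explained 0.513% of the variance across genes and 99.8% of the difference between the medians was left after it was removed. Chromosome 6 had 12 of 20 bins under -0.2, which argues against a change of the whole chromosome and leaves a change of its distal part open. No DNA was measured. KO1 and KO2 share the shifts of chromosomes 1 and 11, so they may descend from 1 cell that differed from the WT culture. But chromosomes also differed between KO1 and KO2, most of all 6 and 8 (median differences 0.10 and 0.07). Others, among them 2 and 12 (-0.036 and 0.037), differed by less. These differences were looked for only after the data were seen, and neither point was tested further.

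All 7 genes tested on chromosome Y kept at most 9.41% of their WT level in both knockouts, which is consistent with loss or silencing of chromosome Y. A line with 2 active X chromosomes is argued against by the X-linked genes, whose higher median log2 fold change was -0.0627. The small remainder may come from reads shared with X-linked paralogs, which was not tested. Whether the loss of Prmt1 or another difference led to it was not tested.

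Some genes differed between KO2 and KO1 in the test of that difference, and so in their effect against WT. Higher in KO2 were Zfy1 (log2 difference 3.51; with 2 counts in KO1 and 26 in KO2, a ratio of 13.2 with an interval of 3.30 to 114), Cdc42bpg (1.59), Sfrp4 (1.36), Tex13 (1.25), Ppp1r14a (1.12), Pax6 (1.10), Ncan (0.90), Lrguk (0.83), Rassf4 (0.76), Egr1 (0.51), Prmt8 (0.43) and Dhcr7 (0.27). Lower in KO2 were Nlrp9b (-1.73), Fam84b (-1.08), Nudt12 (-0.78), Ntn1 (-0.77), Dok2 (-0.68), Igf2 (-0.61), Plpp2 (-0.60), Pcdhgc3 (-0.55), Pth1r (-0.55), Krt18 (-0.54), Aard (-0.53), Cystm1 (-0.45), Zfp57 (-0.44), Krt8 (-0.42), Grhl2 (-0.39), Ddit4 (-0.36), Col4a1 (-0.35), Id1 (-0.35), Perp (-0.32), Col4a2 (-0.31), Grb10 (-0.23) and Socs3 (-0.22). Cdc42bpg, Ppp1r14a, Ncan, Lrguk, Plpp2 and Pcdhgc3 were called against WT in KO2 alone, and Rassf4, Aard, Cystm1 and Zfp57 in KO1 alone. These 10 genes, and Zfy1, Fam84b and Nudt12, each lost the call between KO2 and KO1 in 3 to 6 of the refits without 1 library.

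The single-cell table, which enters no comparison between genotypes, held 109 primitive endoderm-like cells and 84 2-cell-like cells. Both clusters were found in and named from these same cells, so their sizes were not tested.

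Of the 84 splits of the 9 libraries into 6 and 3, only 1, the real one, gave as many genes as the mean contrast. It gave 11449 in a fit of 2 groups, against at most 1 in the others. This argues against chance for these libraries but does not exclude it, since 1 of 84 is the lowest share that these splits can give. Every other split also mixed WT and knockout libraries in a group. Differences between cultures are not covered, since the replicates may not be separate cultures. KO1 and WT gave 10854 genes, against at most 0 in the other splits, KO2 and WT 10638 against at most 0, and KO2 and KO1 462 against at most 3; in each only the real split, 1 of 10, gave as many. With 10 splits a share under 0.05 cannot be reached.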

How the results depend on the processing

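Alternatives that remove chromosome medians were chosen only after the result was seen; the others given in this part were planned. The counts of KO1, KO2 and their mean against WT, and of genes called the same way in both, stayed within 1.5 times under other size factors, filters, tests, groups fitted and chromosome centring, except at a threshold of 1 on the absolute log2 fold change, which by construction lowered them to 4208, 4035, 4247 and 3554. Without 1 library they ran from 10560 to 11370, 10267 to 11071, 11079 to 11753 and 9337 to 9552. A replicate block, though the numbers did not pair the libraries, gave 11017, 10811, 11646 and 9744 genes, a log2 fold change of -2.96 for Prmt1, 247 genes between KO2 and KO1 and 10 lists. Prmt1 ran from -3.01 to -2.90 without 1 library. Of the calls in the mean contrast, 10557 of 11730 kept their direction with chromosome medians removed and 227 were called the other way.

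The difference between KO2 and KO1 was less stable. Against 286 genes, 508 were called without a filter, 498 with DESeq2, 462 in a fit of only these groups, 19 at a threshold of 1 and 107 to 385 without 1 library; apart from the threshold, the cause was not tested. Genes named from this difference itself were refitted without each library; list members named for it were not. Dok2, Nlrp9b, Ntn1, Sfrp4 and Tex13 stayed called in every refit, while Aard, Cdc42bpg, Cystm1, Fam84b, Lrguk, Ncan, Nudt12, Pcdhgc3, Plpp2, Ppp1r14a, Rassf4, Zfp57 and Zfy1 each lost the call at least once, in 56 refits together. Zfy1 lost it in 4 refits and fell from 3.51 to 2.51 without KO2 replicate 1. Lrguk was no longer called with the replicate block (0.83 before and after), and Lrguk (0.74), Rassf4 (0.68) and Cystm1 (-0.41) were no longer called with chromosome medians removed.

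Of the list calls, 10 with the preset correlation, 0 remained with an estimated one, 6 were made at a filter of 5 CPM and 20 with fry, which tests a different question; 10 were made without each library in turn. Lists that were not called changed direction: LIF and STAT3 targets with fry (adjusted p = 0.507) and without WT replicate 1 (adjusted p 0.707 to 0.958 without 1 library), and DNA replication without WT replicate 2 and without KO1 replicate 2 (adjusted p 0.889 to 1.000 without 1 library). With chromosome medians removed, Mcm3 went from 0.49 to -0.022, and Cdc6 (-0.06) and Mcm2 (-0.06) were no longer called. All 117 named genes of the mean contrast kept direction and call under DESeq2, RLE factors, the block and all 1053 refits without 1 library.

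The primitive endoderm-like share of cells was 0.782% to 0.790% at other resolutions, with 4000 variable genes or with another seed. It was 9.32% when cells with at least 3 markers were counted in place of a cluster. Of these markers, Sparc, Lama1 and Lamb1 were detected in 97.3%, 15.6% and 15.0% of cells outside both small clusters. The cause of the higher share was not tested. The alternatives for the level of each gene in WT and knockout single cells were not run, because no label maps cells to libraries: another detection threshold, matched depth, and cells with at least 2000 genes. In simulated data with only 200 changed genes, 94.0% of 2-fold changes and a smaller share of smaller ones were found in the mean contrast.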

Other observations

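No test in this part was chosen after its result was seen except the comparison of single-cell clusters with the bulk fold changes. Genes most enriched in the primitive endoderm-like cells were also higher in bulk: of the top 50, 47 were tested in bulk, 45 were higher in the mean of both knockouts, 0 were lower, and the median log2 fold change was 4.77. For the 2-cell-like cells 29 of the top 50 were tested, 28 were higher, 0 were lower, and the median was 3.47. Among all 17085 genes tested, 34.8% were higher, a share not matched for the level in WT. A gene with almost no counts in WT was tested only where the knockouts held enough counts, and had little room to be lower. This bears most on the 2-cell-like cells, with 29 of 50 genes tested against 47 of 50. The counts for both clusters are therefore descriptive, and no excess over the 34.8% was tested.

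Other clusters also fell mostly to 1 barcode suffix. A cluster of 1101 cells held 1099 with suffix 2, and a cluster of 586 held 585. Within suffix 2, 182 cells had Gata4 detected, of which 105 had 3 or more other primitive endoderm markers detected and 91 lay in the primitive endoderm-like cluster; suffix 1 held 2 cells with Gata4, of which 0 had 3 others.

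Tex14, a germ cell gene, was high in WT replicate 2 (1077 counts, against 361 and 281) and in KO1 replicate 1 (398 counts, against 87 and 113). Replicates differed beyond counting error, with a chi-square per degree of freedom between 4.47 and 14.6 in pairs of libraries of a group.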
